A study of Homo sapiens with 12 samples.

How the data were processed

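Cells of the human lung cancer lines A549 and NCI-H460 (H460) were grown under normoxia or hypoxia for 24 h, per the labels, and total RNA was labelled with Cy3 and hybridised to 12 one-colour arrays, 3 in each of 4 groups. The deposited scanner files hold, per the file headers, the intensity of every spot as Agilent Feature Extraction 11.0.1.1 gave it, with background subtracted and no normalization between arrays. Other columns of these files hold 0 or 1 flags of the scanner software for spot quality, which are a unit of other kind per the file headers. The deposited value table of the authors holds log2 values of 45021 probes. The authors did not state its normalization. Its array medians lie between 6.68 and 6.69, and its values differ by 0.0041 at the median from quantile-normalized log2 intensities computed here. All of its probes passed the filter described below, which also kept the 20 probes with a gene name and 1 further probe without one.

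Each array had 62903 spots. The 1439 spots marked as controls were set aside, and so were 60 probes (360 spots) whose names begin with Negative and which the files do not mark as controls. The log2 intensities of the spots of a probe were averaged, leaving out spots marked as outliers, which gave 60924 probes. Of these, 20 carried a RefSeq accession, and all 20 matched a gene symbol in the reference table. Each of these 20 was printed on 10 spots, and for the 18 brightest the SD between spots on an array had a median of 0.0245 and a maximum of 0.0852 (log2). The 75th percentile of each array was subtracted. It ranged from 194.9 to 418 intensity units between arrays, between 60.44% and 71.35% of probes lay well above background, 0 non-control spots were saturated, and 27 to 212 spots an array were marked as outliers. Probes marked well above background on at least 3 of the 12 arrays were tested, 45042 in all, and 32588 were so marked on all 12. An outlier spot left 433 tested probes without a value on some array. Replicate arrays had a Pearson r across probes of 0.989 to 0.991 in both A549 groups, 0.970 to 0.978 in H460 hypoxia and 0.986 to 0.990 in H460 normoxia. No array was a copy of another within its group.

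One model with 4 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, using moderated statistics, a shared spread and two-sided tests. The comparisons were hypoxia minus normoxia in each line, the difference of these (A549 minus H460), and A549 minus H460 under normoxia. A probe counted as changed with a Benjamini-Hochberg adjusted p under 0.05 over the probes of that comparison and a change of at least 2-fold, and a named gene was said to rise or fall with an adjusted p under 0.05 at any fold. Overlap between lines was tested with Fisher's exact test. Files were read with the R package data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The array design was built on hg19 per the file headers, and no coordinates are given because the reference table uses another build. The model, the filter, the thresholds, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, apart from those named as later in each part.

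The rule for named genes took probes with a gene symbol, changed as above, with the arrays of one group all on one side of those of the other and well above background on all 3 arrays of at least 1 group, ranked by size. It gave PGK1 in A549, PGK1 and ODC1 in H460, PGK1 for both lines, and RPL10 among those for the comparison under normoxia. The values of 2 of the 20 genes are not given and these genes are not drawn, but they count in the totals over the 20. The other named genes were chosen after their values were seen, as members of the fixed lists, as genes past the adjusted p alone or as the ends of a range. The 4 probes given by identifier were also chosen after their values were seen, with the same conditions applied to probes without a symbol. Of the 24 fixed gene lists with 508 genes, 3 had a measured member: glycolysis with 2 of 23, cytosolic ribosomal proteins with 3 of 30 and the respiratory chain with 1 of 34. Set tests, for which at least 80% of a list was required, were therefore not run. The split into long noncoding and messenger RNAs was not run because no file gives the class of a probe.

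Alternatives were quantile normalization, normexp background correction with an offset of 50, scaling to the median, 3 other filters on dim probes, 2 other thresholds, each line alone, the replicate number as a block with and without a stricter filter, the authors' table, a trended and robust prior, array weights, scan as a block, and each array left out in turn. The normexp alternative was planned on mean signals, which the files do not hold, so median signals were used. The scan of an array was taken from the file headers: 8 arrays belonged to 1 scan and 4 to another. On simulated data with 200 changed probes and the same spread in both lines, the model recovered 76.5% of them in A549 and 77.0% in H460, and 7 of 160 and 5 of 159 calls were false. When each line had the spread of its own arrays, 14 of 184 calls in A549 and 46 of 207 in H460 were false (7.61% and 22.2%). No simulation was run near the real H460 count, so the share of false calls there was not estimated. With each line fitted alone the false calls were 8 of 178 in A549 and 11 of 136 in H460. The version of this check with unequal spreads was written first and failed its own limit on false calls, and the version with equal spreads was added after that was seen.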

Results

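Total RNA was measured on 12 one-colour microarrays from A549 and NCI-H460 (H460), both established human lung cancer cell lines. The A549 line derives from a lung adenocarcinoma and the H460 line from a large cell lung carcinoma. Cells of each line were kept for 24 h under normoxia or under hypoxia in medium with 10% serum, which gave 4 groups of 3 arrays. The labels did not state the oxygen level. They also did not say whether the 3 arrays of a group came from separate cultures, so each p-value below measures only the spread between these arrays. Between 60.44% and 71.35% of the 60924 non-control probes lay well above background on an array, and the number of arrays limits the precision. The series was made to find long noncoding RNAs regulated by hypoxia, but only 20 of the probes carried a gene accession, and these 20 probes matched 20 genes. The other 60904 probes had an array identifier alone, and no file stated which of them detect long noncoding RNAs. None of the probes with a gene name belonged to the hypoxia markers CA9 and VEGFA, to the oxygen-sensing factors HIF1A and EPAS1, or to the noncoding RNAs MIR210HG, MALAT1, NEAT1 and H19, so no value could be given for these genes.

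The first comparison asked which transcripts differed between hypoxia and normoxia in A549 cells. PGK1, an enzyme that makes ATP in glycolysis, rose under hypoxia to a log2 signal of 5.10 ± 0.132 (SD, n = 3) from 3.29 ± 0.213 (SD, n = 3) under normoxia, relative to each array's 75th percentile. This was a 3.51-fold rise (one standard error to either side, 3.12 to 3.95), with an adjusted p of 4.15e-04 in limma and with all 3 hypoxia arrays above all 3 normoxia arrays. GAPDH, the glycolytic enzyme that precedes PGK1 in the pathway, differed by 0.05 (log2, SE 0.163) on its named probe. This did not pass (adjusted p = 0.918 in limma), and its arrays overlapped. Of the human GAPDH control probes, Human-GAPDH_5 rose by 0.69 (adjusted p = 0.0064 in limma, over the control probes). Human-GAPDH_3 differed by 0.19 and did not pass (0.445), so the named probe does not settle whether GAPDH changed. ODC1, the rate-limiting enzyme of polyamine synthesis, differed by -1.25 (log2, SE 0.356), a 2.38-fold lower mean with all 3 hypoxia arrays below all 3 normoxia arrays, and did not pass in limma (adjusted p = 0.0888). It passed in 6 alternatives, among them A549 arrays alone (adjusted p = 0.0104 in limma) and all arrays without H460 hypoxia replicate 2 (0.0127), over a range of 0.00645 to 0.263. By the named probes, 1 of the 2 measured members of the glycolysis list rose over all probes tested, and 1 when adjusted over the list alone. The 3 measured ribosomal protein genes, RPL10, RPLP1 and RPS18, differed by -0.05, -0.10 and -0.11, and COX4I1, the 1 measured gene of the respiratory chain list, by -0.08. None of these 4 passed in limma, over all probes or over its list alone, and under other scalings RPL10 and RPLP1 took the opposite sign. ACTB, a cytoskeletal actin often used as a reference gene, differed by -0.13 and lost its sign under quantile normalization. Over the 20 named genes 1 rose, 0 fell and 19 did not pass, the latter lying between -1.25 for ODC1 and 0.05 for GAPDH.

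Among the probes without a gene name, ASHGV40001384 had the largest rise in A549 cells, 7.09 (log2, SE 0.578), which is 136-fold, with an adjusted p of 1.96e-04 in limma. Among probes that fell, whose arrays did not overlap and that lay well above background on all 3 arrays of at least 1 group, ASHGV40032426 had the largest fall, -2.49 (SE 0.226), or 5.64-fold, with an adjusted p of 3.33e-04 in limma. The 3 hypoxia arrays lay on one side of the 3 normoxia arrays for both probes. In total 665 of 44971 probes changed at least 2-fold in A549 cells with an adjusted p under 0.05 in limma, 441 upwards and 224 downwards. Without the minimum fold 650 rose and 690 fell. Of the 665, 117 changed at least 4-fold, 104 of them upwards. In 80 of the 665, 1 of the groups had no array well above background, so that the fold is a rough value there. The median over all probes was -0.11 (log2). The groups did not overlap for 32% of the probes, where chance gives 10%. Each of the 6 A549 arrays mattered for this count, which fell to 367, 374 and 325 without hypoxia replicates 1, 2 and 3 and to 340, 325 and 493 without normoxia replicates 1, 2 and 3.

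The second comparison asked the same of H460 cells. PGK1 rose 3.04-fold (one standard error to either side, 2.70 to 3.42), from 3.94 ± 0.164 to 5.54 ± 0.200 (log2, SD, n = 3 in each group), with an adjusted p of 2.52e-04 in limma and all 3 hypoxia arrays above the normoxia arrays. GAPDH rose 1.5-fold (log2 0.59, SE 0.163, adjusted p = 0.0307 in limma), again with the 3 hypoxia arrays above the 3 normoxia arrays. ODC1 fell 4.85-fold (log2 -2.28, SE 0.356, adjusted p = 0.00193 in limma), and ARHGDIA fell 1.77-fold (log2 -0.83, SE 0.179, adjusted p = 0.00971 in limma). All 3 hypoxia arrays lay below the 3 normoxia arrays for both genes. The 2 measured members of the glycolysis list therefore both passed as rises after this scaling, over all probes and adjusted over the list alone. RPLP1, RPS18 and RPL10 differed by 0.41, 0.37 and -0.21 and COX4I1 by 0.26, and none of these 4 passed in limma over all probes or over its list alone. Under quantile normalization RPS18 and COX4I1 took the opposite sign, as did ACTB, which differed by 0.27 without passing. Over the 20 named genes 2 rose, 2 fell and 16 did not pass, the lowest of the latter being DYNLL1 at -0.56. DYNLL1 passed in 4 of 25 alternatives, among them the one without hypoxia replicate 2 (-0.81, adjusted p = 0.0132 in limma). RPLP1 passed in 1 of 25, without hypoxia replicate 3 (0.57, adjusted p = 0.0471 in limma).

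The scan of the arrays followed the groups in part in H460 cells, because the 3 hypoxia arrays and normoxia replicate 3 formed 1 scan and normoxia replicates 1 and 2 belonged to the other. With scan as a block, PGK1 differed by 1.5 (adjusted p = 0.0158 in limma), ODC1 by -2.12 (0.0619), ARHGDIA by -0.73 (0.169) and GAPDH by 0.48 (0.310), so that only the PGK1 call was kept. The second scan holds 1 H460 normoxia array, too few to compare the groups within it, and the values with scan as a block rest on that same array. The GAPDH rise was also 0.18 under quantile normalization (adjusted p = 0.338 in limma). It did not pass with H460 arrays alone (adjusted p = 0.146 in limma), nor did ARHGDIA (0.0935). GAPDH also did not pass without hypoxia replicate 1 (0.49, adjusted p = 0.0791 in limma) or without normoxia replicates 1, 2 or 3 (0.54, 0.58 and 0.64, with adjusted p of 0.0911, 0.0927 and 0.0538). In all, the GAPDH call in H460 was lost in 12 of 25 alternatives, not all of them named here.

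Probe ASHGV40001384 had the largest rise in H460 cells too, 7.52 (log2, SE 0.578), which is 184-fold, with an adjusted p of 4.21e-05 in limma. ASHGV40017163 came next with 6.13 (SE 0.467), or 69.9-fold, and an adjusted p of 4.04e-05 in limma, and by the same conditions as in A549 cells ASHGV40031207 had the largest fall, -3.77 (SE 0.429), or 13.7-fold, with an adjusted p of 3.65e-04 in limma. With one array left out these 3 differences ran from 6.72 to 8.28, 5.62 to 6.74 and -4.40 to -3.33, and the normoxia SD of ASHGV40001384 was 1.57 (log2, n = 3). Over all alternatives ASHGV40017163 ran from 4.63 to 6.74 and ASHGV40031207 from -4.40 to -2.38. The hypoxia arrays lay on one side of the normoxia arrays for these 3 probes, and with scan as a block their differences were 7.43, 6.01 and -3.82 with adjusted p of 0.00403, 0.00403 and 0.0158 in limma. In total 3881 of 45027 probes changed at least 2-fold with an adjusted p under 0.05 in limma, 1667 upwards and 2214 downwards. Of these, 554 changed at least 4-fold, 349 of them upwards, and in 585 of the 3881 1 of the groups had no array well above background. The median over all probes was -0.08 (log2), and the groups did not overlap for 29.2% of the probes, where chance gives 10%. With scan as a block 1183 probes were called. The balance of directions depended on the processing: rises exceeded falls with scan as a block (651 against 532), with H460 arrays alone (1056 against 997) and in the authors' table (1976 against 1911). The H460 hypoxia arrays varied more than the other groups, with a median probe SD of 0.353 against 0.163 in A549 hypoxia, 0.196 in A549 normoxia and 0.209 in H460 normoxia.

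**Figure D1:**
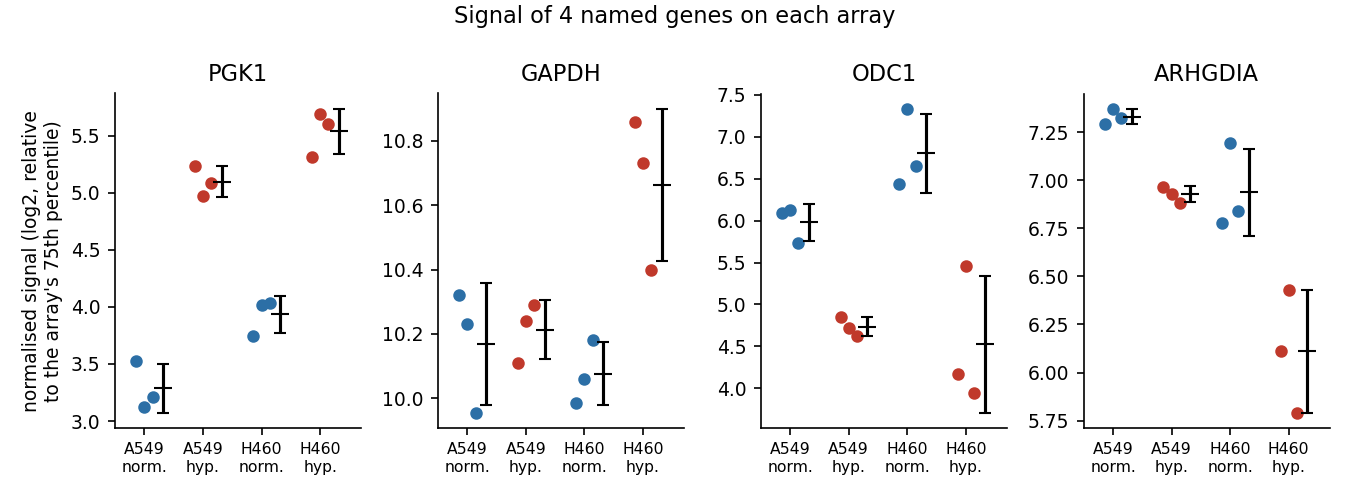
Signal of PGK1, GAPDH, ODC1 and ARHGDIA on each of the 12 arrays (log2, relative to the array's 75th percentile), with points for arrays, blue for normoxia, red for hypoxia and black bars for the mean and SD of each group; the vertical scale differs between panels and does not start at 0. PGK1 lies higher on the hypoxia arrays of both lines, and ODC1 lies lower, a difference that passed the test in H460 and not in A549.

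**Figure D2:**
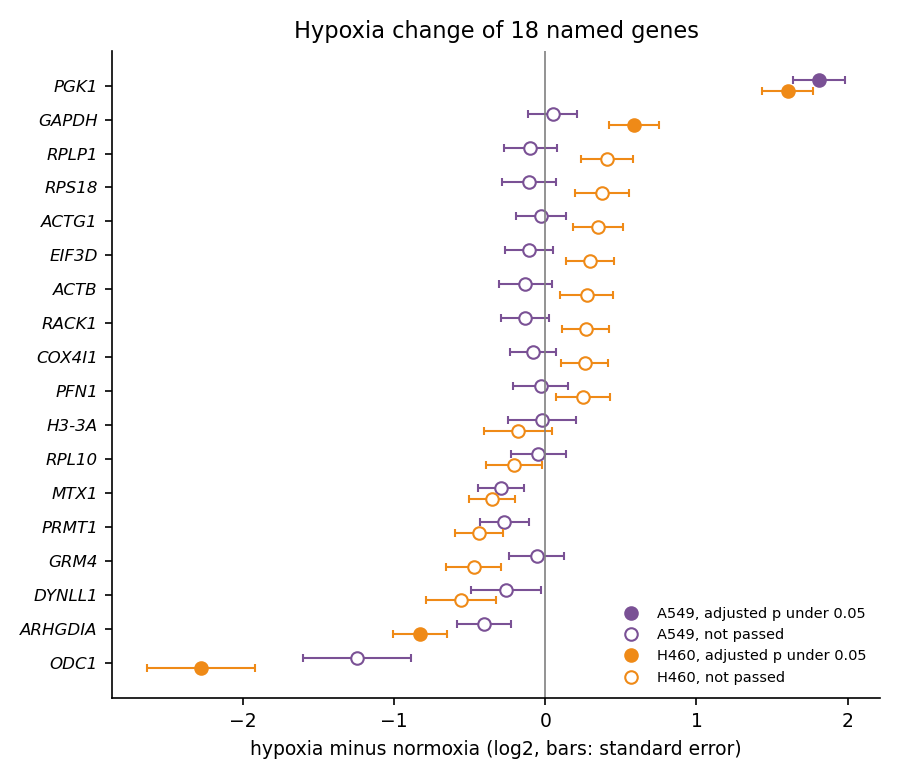
Difference between hypoxia and normoxia (log2) for 18 of the 20 named genes in A549 (purple) and H460 (orange), 3 arrays against 3 in each line, with bars for the standard error and filled points for an adjusted p under 0.05 in limma. PGK1 is filled in both lines, and GAPDH, ARHGDIA and ODC1 in H460 alone; under at least 1 other scaling 7 of the 18 genes in A549 and 7 in H460, all open points, take the opposite sign, and under quantile normalization the GAPDH call is lost.

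The third comparison asked which changes the lines shared and which differed between them. PGK1 rose in both, and its rise did not differ detectably between them (A549 minus H460 0.21, SE 0.240, adjusted p = 0.724 in limma). The largest rise in both lines was that of the same unnamed probe, ASHGV40001384, again with no detectable difference between the lines (-0.44, SE 0.818, adjusted p = 0.838 in limma). The named probes of GAPDH, ODC1 and ARHGDIA passed in H460 and not in A549. Their difference between the lines was -0.54 (SE 0.231), 1.03 (SE 0.503) and 0.42 (SE 0.253). None of the 3 passed (adjusted p of 0.283, 0.349 and 0.452 in limma), so none of these genes was shown to respond differently in the lines. The control probe Human-GAPDH_5 rose in both lines (0.69 in A549 and 1.08 in H460). Without H460 hypoxia replicate 2 the ODC1 difference was 1.5 and passed (adjusted p = 0.0274 in limma), and with array weights it was 1.45 and passed (adjusted p = 0.0336 in limma). Over the 20 named genes the highest difference between the lines was that of ODC1, and 0 of the 20 passed over all probes tested in limma, and 0 of the glycolysis, ribosomal and respiratory members passed adjusted over their lists alone.

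Some unnamed probes did differ between the lines. ASHGV40032426, which fell in A549 cells, differed by 0.26 in H460 cells (adjusted p = 0.487 in limma), and the difference between the lines was -2.75 (SE 0.319, adjusted p = 0.0035 in limma). ASHGV40017163, which rose 69.9-fold in H460 cells, differed by 1.90 in A549 cells (adjusted p = 0.0544 in limma), with a difference between the lines of -4.22 (SE 0.661, adjusted p = 0.0133 in limma). ASHGV40031207 differed by -0.38 in A549 cells (adjusted p = 0.720 in limma), with a difference of 3.39 (SE 0.607, adjusted p = 0.0236 in limma). With scan as a block these 3 differences were -2.73, -4.10 and 3.44 with adjusted p of 0.0449, 0.117 and 0.157 in limma, so only the first still passed. In A549 cells ASHGV40017163 passed in 10 of 26 alternatives (adjusted p of 0.00254 to 0.176 in limma over all 26), among them those without H460 hypoxia replicates 1 or 2 (0.0217 and 0.00807). The difference for ASHGV40031207 did not pass without any one of 7 arrays (3.22 to 3.44, adjusted p of 0.0555 to 0.0664 in limma): A549 hypoxia replicates 1, 2 and 3, A549 normoxia replicates 1 and 3, and H460 normoxia replicates 2 and 3.

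Of the 441 probes that rose in A549 cells, 229 also rose in H460 cells, where independent lists would share 16.4, and 7 fell. Of the 224 that fell, 63 also fell in H460 cells, where independent lists would share 11, and 7 rose. The odds ratio was 32.4 (95% interval 26.6 to 39.6, two-sided Fisher's exact p = 2.9e-207) for rises and 7.76 (5.69 to 10.5, p = 2.5e-30) for falls; probes are not independent replicates, so these p-values are a description. Across 44965 probes the log2 changes of the lines had a Pearson r of 0.389 and a Spearman rank correlation of 0.352. Of the 665 probes called in A549 cells, 359 were not called in H460 cells, yet only 75 of those had a called difference between the lines. Of the 3881 called in H460 cells, 3575 were not called in A549 cells, and 403 of those had a called difference. The change itself differed between the lines for 638 probes in limma, 218 with the higher value in A549 cells and 420 with the higher value in H460 cells. With scan as a block 73 such probes and 171 shared probes were called. Leaving out H460 hypoxia replicate 2 raised the count of differing probes to 2716. Without H460 hypoxia replicates 1 and 3 it was 665 and 548. Leaving out an A549 array or an H460 normoxia array lowered it: to 314, 213 and 221 without A549 hypoxia replicates 1, 2 and 3, to 259, 278 and 312 without A549 normoxia replicates 1, 2 and 3, and to 379, 301 and 345 without H460 normoxia replicates 1, 2 and 3. The shared count fell to 133, 167 and 140 without A549 hypoxia replicates 1, 2 and 3 and to 154, 140 and 180 without A549 normoxia replicates 1, 2 and 3.

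**Figure D3:**
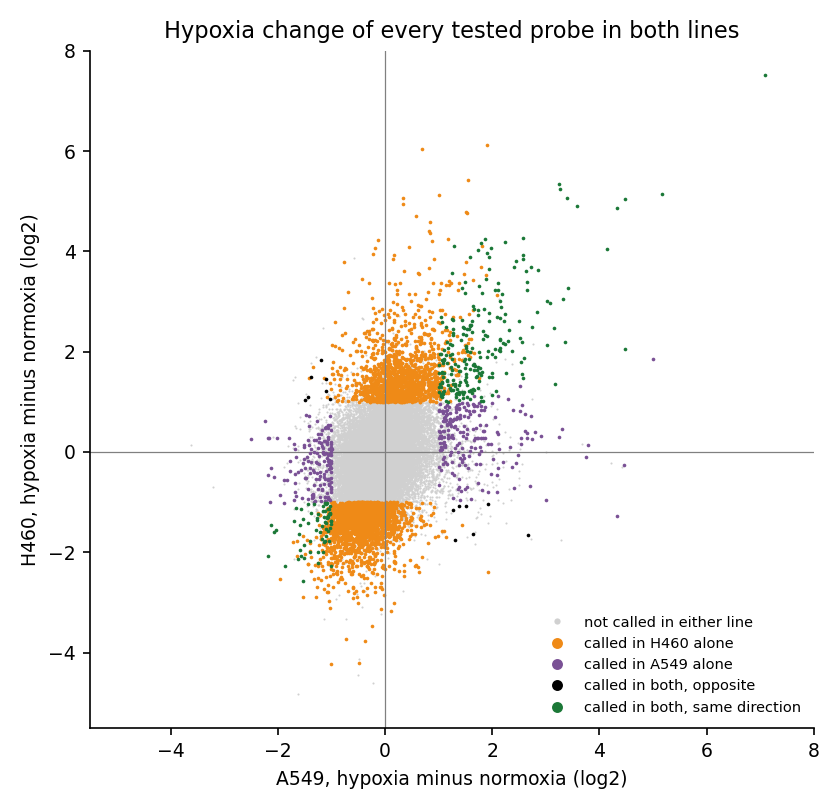
Difference between hypoxia and normoxia (log2) of every tested probe in A549 (horizontal axis) and in H460 (vertical axis), 1 point per probe, 3 arrays against 3 in each line. Green points changed in both lines in the same direction (292 probes), black points in opposite directions (14), purple points were called in A549 alone (359) and orange points in H460 alone (3575); the point at the upper right is ASHGV40001384.

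The fourth comparison set the lines side by side under normoxia, as the background to their responses. RPL10, a protein of the large ribosomal subunit, was 2.24-fold lower in A549 cells (log2 -1.16, SE 0.184, adjusted p = 4.88e-04 in limma). Its probe was dim, with normoxia means of -1.77 in A549 and -0.61 in H460 (log2), against 10.45 and 10.35 for RPLP1. How well this probe reports the RPL10 transcript was not tested. The arginine methyltransferase PRMT1 was 1.78-fold higher in A549 cells (log2 0.83, adjusted p = 0.00198 in limma), the dynein light chain DYNLL1 1.89-fold (0.92, 0.0104) and the actin-binding protein PFN1 1.51-fold (0.59, 0.0285). PGK1 was 1.57-fold lower in A549 cells (log2 -0.65, adjusted p = 0.0128 in limma). The PGK1 control probes differed in the same direction, by -0.29 (Human-PGK1_3) to -0.58 (Mouse-PGK1_5). None of them passed over the control probes (adjusted p of 0.119 to 0.202 in limma). The 3 arrays of one line lay on one side of the 3 arrays of the other for RPL10, PRMT1, DYNLL1, PFN1 and PGK1. ODC1 differed by -0.82 and did not pass (adjusted p = 0.112 in limma), although it passed under quantile normalization (-1.08, 0.0264), with array weights (-0.83, 0.0272), without H460 hypoxia replicate 2 (0.0165) and in the first scan alone (-0.90, 0.0319). Of the 20 named genes 4 were higher in A549 cells, 2 were lower and 14 did not pass, between -0.82 for ODC1 and 0.39 for ARHGDIA. GAPDH differed by 0.09 and took the opposite sign under quantile normalization. Of the 3 ribosomal genes 1, RPL10 with its dim probe, was lower, over all probes and adjusted over the list alone. Of the 2 glycolysis genes 1 was lower on either count, and COX4I1 did not pass.

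In total 7936 of 44998 probes differed at least 2-fold between the lines under normoxia in limma, 3756 higher and 4180 lower in A549 cells, and 3051 of them at least 4-fold. The balance reversed with scaling to the median (4245 higher and 3764 lower), with normexp (2475 and 2241) and without a minimum fold (6653 and 6587). The groups did not overlap for 46.5% of the probes, where chance gives 10%. In 1393 of the 7936, 1 line had no array well above background. With scan as a block 7680 probes were called, and 8055 in the first scan alone. The second scan holds 1 normoxia array, H460 normoxia replicate 3, so for this comparison the scan block only takes that array out. It gave the same counts and values as the fit without that replicate and is no separate check of the scan. In this fit the PFN1 difference was 0.57 (adjusted p = 0.0811 in limma) and the PGK1 difference -0.60 (adjusted p = 0.0509), and neither passed. PFN1 also did not pass without A549 normoxia replicates 1 or 2 or H460 normoxia replicate 1 (0.52, 0.60 and 0.57, with adjusted p of 0.104, 0.0687 and 0.0809 in limma). PGK1 also did not pass without A549 normoxia replicate 2 (-0.56, adjusted p = 0.0571 in limma).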

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

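For the larger count in H460, the test of a single deviating array was narrowed after its values were seen, and the tests on the GAPDH control probes were chosen only after the result was seen; the other tests in this part were set before their results were seen.

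Several control probes for PGK1 and GAPDH, which are not part of the comparisons, rose under hypoxia with an adjusted p under 0.05 over the 51 control probes tested. In A549 cells the rises (log2) were 1.55 for Human-PGK1_3, 1.75 for Human-PGK1_5, 2.19 for Mouse-PGK1_3, 1.79 for Mouse-PGK1_5, 1.80 for Rat-PGK1_5, 0.69 for Human-GAPDH_5 and 0.80 for Rat-GAPDH_5. In H460 cells they were 1.58 for Human-PGK1_3, 1.43 for Human-PGK1_5, 2.33 for Mouse-PGK1_3, 1.44 for Mouse-PGK1_5, 1.45 for Rat-PGK1_5, 0.65 for Human-GAPDH_3, 1.08 for Human-GAPDH_5, 1.79 for Mouse-GAPDH_3, 1.37 for Rat-GAPDH_3 and 1.23 for Rat-GAPDH_5. Other GAPDH control probes did not pass: in A549 cells Human-GAPDH_3 (0.19, adjusted p = 0.445 in limma), Mouse-GAPDH_3 (0.81, 0.106), Mouse-GAPDH_5 (0.12, 0.561) and Rat-GAPDH_3 (0.47, 0.248), and in H460 cells Mouse-GAPDH_5 (-0.16, 0.503). Negative047, named as a negative control, was 1.78 higher under hypoxia in H460 cells (0.88 ± 0.635 against -0.90 ± 0.613, log2, SD, n = 3) and lay well above background on all 12 arrays. Other control probes fell with an adjusted p under 0.05: in A549 cells DCP_22_7 by -0.66 and ERCC-00097_63 by -0.65 (log2), and in H460 cells Negative022 by -1.43, ERCC-00097_63 by -1.06, Negative050 by -0.83, Negative039 by -0.80, ETG09_35454 by -0.76 and ERCC-00104_60 by -0.58. The change under hypoxia differed between the lines for 638 probes.

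GAPDH rose by different amounts on different probes. In A549 cells the named GAPDH probe differed by 0.05 without passing, while Human-GAPDH_5 rose by 0.69, and the signed difference of the Human-GAPDH probes, suffix 5 minus suffix 3, went from -0.95 under normoxia to -0.45 under hypoxia in A549 (a move of 0.51, SE 0.0896) and from -0.99 to -0.56 in H460 (0.43, SE 0.162), so the probes came closer. In A549 and H460 the same signed difference moved by -0.69 and -1.95 for Mouse-GAPDH and by 0.33 and -0.14 for Rat-GAPDH. For Mouse-PGK1 it moved by -0.41 and -0.89. In both of these GAPDH pairs 1 probe was dim, Mouse-GAPDH_5 at 108 to 216 units and Rat-GAPDH_3 at 86.7 to 182 (group means). These probes are named for mouse and rat and the RNA was human, so they do not show whether the shift is general. A shift of RNA quality with hypoxia stays open, since the Human-PGK1 difference, which moved by 0.196 (SE 0.112) in A549 and -0.15 (SE 0.307) in H460, does not lie more than 2 SE under the bound of 0.3 in either line. Compression of the brightest signals stays open as the cause. Between replicate arrays of unequal brightness, probes above 200000 units differed by -0.275 to 1.24 times as much as middle ones over 7 pairs. The named GAPDH probe, looked at after its values were seen, moved less than middle probes in each of the 7 pairs. On H460 hypoxia replicates 1 and 3 its log2 signal was 18.47 and 18.72, where middle probes differed by 0.703. This goes with compression at the brightness of that probe, but whether it explains the GAPDH differences was not tested. The files do not say what the suffixes mean, and a difference between parts of the GAPDH transcript was not tested.

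More probes changed in H460 cells (3881) than in A549 cells (665). With scan as a block the counts were 1183 and 530. All A549 arrays belong to 1 scan, so the block leaves the A549 changes as they were. For A549 it is the same fit as the one without H460 normoxia replicate 3, which also called 530. A scan effect shared by the H460 hypoxia arrays stays open: the slope of scan-adjusted on unadjusted changes of the called probes was 0.970 with all arrays (median size 1.38 before and 1.35 after, median SE 0.272 and 0.390) and 0.967 at its lowest with each hypoxia array left out, above the bound of 0.8 set beforehand, but that bound was wrong because the scan term rests on 1 normoxia array. One deviating array was not needed, since the H460 count stayed at least 3.78 times the A549 count without any one H460 hypoxia array, and with each line fitted alone it was 2.12 times. Part of the gap may come from the shared spread, since the ratio was 5.84 in the joint model and 22.2% of H460 calls were false in a simulation with 200 changed probes and each line's own spread. Lower quality of H460 hypoxia replicates 1 and 2 together stays open. Their array weights were 0.262 and 0.234, against 2.21 for replicate 3, the highest of the 12 arrays, and the median probe SD of the group was 0.353. With these weights 5096 probes were called in H460 and 1200 in A549, but that fit leans on replicate 3 and does not settle the question. A larger response of H460 cells to hypoxia also stays open and was not tested.

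For the counts in each line and under normoxia the 10 splits of the 6 arrays are too few for a share under 0.05. The real split, 1 of the 10 in each case, gave 665 probes in A549 against at most 2 in another split, 3881 in H460 against at most 78, and 7936 under normoxia against at most 0. Every other split mixes arrays of the compared groups, which adds any real difference to the spread and lowers the calls. The size of these gaps is therefore no measure of support. For the 638 probes that differed between the lines, 4 of 100 drawn splits, the real one included, gave as many, out of 200 possible, with 1116 as the highest other. The 90 splits that regrouped the H460 arrays removed the H460 effect and reached at most 69. The 9 others, of which 3 gave as many, set the full H460 effect against regrouped A549 arrays, so a difference is built into them, and the splits do not test whether chance explains the 638. For the 292 shared probes 1 of 100 splits, the real one, gave as many, with 1 probe as the highest other. A regrouped line calls too few probes to share as many (at most 2 in A549 and 78 in H460), so this does not test the sharing.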

How the results depend on the processing

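The alternatives with a single scan and with bright signals left out were chosen only after the result was seen. The counts for A549, H460, their difference, normoxia and shared probes were 665, 3881, 638, 7936 and 292. Normexp gave 434, 2100 and 4716 (A549, H460, normoxia); no filter on dim probes, 369 (difference); no minimum fold, 1340, 7625, 13240 and 714 (shared); an adjusted p under 0.01, 282, 2432, 116 (difference) and 126 (shared); H460 arrays alone, 2053; the replicate block, 270 (difference); array weights, 1200 (A549), 2738 (difference) and 477 (shared); scan as a block, 1183 (H460), 73 (difference) and 171 (shared); and the second scan alone, 1 (H460; 1 normoxia array, too few for a test). With one array left out the counts ran from 325 to 908, 2613 to 5506, 213 to 2716, 7571 to 8091 and 133 to 435. With another threshold the change follows from the setting. Without H460 hypoxia replicate 2 the counts rose to 908, 5506, 2716, 8091 and 435. The A549 and normoxia comparisons do not use that array, so their rises to 908 and 8091 follow from the shared estimate of the spread. With A549 arrays alone 967 probes were called. For the other changes the cause was not tested. Whether the numbers of the replicates pair arrays was not settled. Same-number deviations had an r of -0.152 to 0.141 in A549 and -0.0154 to 0.148 in H460. The best match had the same number for 1 A549 hypoxia array and 2 H460 hypoxia arrays. With that block the A549, H460 and shared counts were 547, 3829 and 260.

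Median scaling raised the share of rises among the A549 changes from 66.3% to 80.3% and moved the median of all probes under normoxia to 0.11. Normexp moved it to 0.14 in H460 and -0.24 for the difference. The alternatives tallied next are not independent checks, so the tallies overstate how far a call was tested. Leaving out an array that a difference does not use keeps its value and acts only through the shared spread. For the A549 and normoxia differences, scan as a block is the same fit as the one without H460 normoxia replicate 3. Of 250 alternatives for the 10 named differences given here that passed, 224 kept the call, 26 lost it and 0 changed sign. Of 515 for 21 that did not pass, 18 passed and 11 changed sign; the cause was not tested. These 11 were ACTB (A549 6.18e-06, H460 -0.14), COX4I1 (H460 -0.13), RPS18 (H460 -0.0365), RPLP1 (A549 0.0085) and GAPDH (normoxia -0.0357) under quantile normalization; RPL10 (A549) under median scaling at 0.0337 and without hypoxia replicate 2 or normoxia replicate 1 (one array left out, -0.130 to 0.0731); and in A549 GAPDH without normoxia replicate 3 (-0.0587 to 0.123) and COX4I1 without normoxia replicate 1 (-0.153 to 0.00165). Over all 20 named genes and 4 comparisons 58 of 1944 changed sign, 26 of them under quantile normalization and 58 in differences that did not pass. ACTB and GAPDH under normoxia were for a time left out of the reported genes after their sign changes were seen, and were then put back. For the 4 unnamed probes 284 of 306 stayed called or stayed not called, 11 lost a call, 10 gained one and 1 changed sign (ASHGV40001384, difference between lines, -1.2 to 0.37 with one array left out, positive without H460 normoxia replicate 2). Of the changed probes, 80 in A549 and 585 in H460 had no array well above background in 1 group.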

Other observations

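The overlap of probes detected in 1 condition and the test of the signal floor were chosen only after the result was seen; the other tests in this part were set before their results were seen.

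Some transcripts were detected in 1 condition alone. In A549 cells 33 probes lay well above background on all 3 hypoxia arrays and on 0 normoxia arrays, and 18 of these were called as rises; in H460 cells this held for 79 probes, of which 59 were called. Of these called probes, 2 were the same in both lines, where independent lists would share 0.0236 (odds ratio 98.4, 95% interval 10.7 to 438, two-sided Fisher's exact p = 2.5e-04). The reverse was more frequent: 245 probes in A549 and 539 in H460 were detected on all 3 normoxia arrays and on 0 hypoxia arrays. Of these, 21 and 282 were called as falls, and 2 were the same in both lines, where independent lists would share 0.131 (odds ratio 16.8, interval 1.89 to 70.2, exact p = 0.0076). None of these probes had a gene name. The independent lists were taken over all tested probes, but 32588 of 45042 lay well above background on all 12 arrays. Those could not enter any of these lists, so the expected overlaps are too low and the odds ratios too high. Each overlap also rests on 2 probes, so these p-values do not test the sharing. The lowest signal marked as well above background was 17.31 to 22.44 units on the A549 hypoxia arrays and 13.97 to 15.55 on the A549 normoxia arrays, and in H460 it was 12.67 to 16.52 under hypoxia and 12.26 to 18.26 under normoxia. The H460 hypoxia arrays were also dimmer, with 75th percentiles of 194.9, 240.8 and 318.2 for replicates 1, 2 and 3 against 397.7, 343.9 and 275.3 under normoxia. Detection in 1 condition is therefore not by itself a measure of rises or falls in either line.

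In A549 cells the changes of at least 4-fold were mostly rises, 104 of 117 (88.9%). A signal floor that hides falls would bring the share towards balance where a fall can be measured. Among the 44 of these probes whose normoxia level lay at least 16-fold above the floor, however, 38 were rises (86.4%, Wilson 95% interval 73.3 to 93.6). Probes are not independent replicates, so this interval is a description of these probes and does not measure the spread between arrays or cultures. Under other scalings the share was 92.7% with scaling to the median, 94.0% with quantile normalization and 98.0% with normexp. The 88.9% was lower than each of these, so the choice among these scalings did not raise it. Scaling to the median and quantile normalization moved the median A549 change from -0.112 to -0.032 and -0.0465, which by itself favours rises. Normexp moved that median to -0.132 and left 49 changes of at least 4-fold. A lower share was thus unlikely from the start with the first 2. The floor result goes with transcripts that rise further than they fall in A549 cells after 24 h of hypoxia, a hypothesis that was found and tested on the same data.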
